A study of Homo sapiens with 26 samples.

How the data were processed

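RNA sequencing of MV4-11 cells, an established human acute myeloid leukaemia line with an activating FLT3 mutation, was taken from 26 libraries in 2 experiments. The first experiment, called the recovery experiment here, held 8 libraries in 4 groups of 2: untreated cells, cells that survived 48 h in 100 nM quizartinib (a FLT3 kinase inhibitor), and such survivors after 13 or 30 days of culture in drug-free medium. The second experiment, called the drug experiment here, held 18 libraries in 6 groups of 3: DMSO, 100 nM dexamethasone (a synthetic glucocorticoid), 10 nM quizartinib and the combination of both, all at 48 h, and quizartinib and the combination at 5 days. In the 5 day combination, per the labels, dexamethasone was added on day 3. The drug experiment has no DMSO or dexamethasone group at 5 days, so the 5 day quizartinib cells could be set only against DMSO cells of 48 h. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so every p measures the spread between these libraries.

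The deposited tables of the drug experiment hold whole-number counts per gene, and their library totals differ, so the counts were taken as not normalised. Per the submitters' processing notes, CASAVA, STAR 2.7.3, RSEM, edgeR and DESeq2 were used with the build GRCh38. The notes give no role or order for these tools and do not state how estimates became whole numbers. The deposited tables of the recovery experiment hold FPKM (fragments scaled by transcript length and by the mapped fragments of the library) per gene and library, per the file headers. Per the submitters' processing notes, CASAVA, TopHat2 2.0.9 and Cuffdiff were used with the build hg38 (GRCh38), and the scaling between libraries is not stated. An FPKM of exactly 0 may also be a failed estimate, so such a gene is described as listed at 0 and has no fold.

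Total counts per library of the drug experiment ran from 14795190 to 24990476. Its tables list 16430 genes, and each has reads in at least 4 libraries. The files name 14051 of these entries, a further 2161 were named from the reference annotation by their Ensembl identifier, and 218 kept the identifier alone. Among all entries, 8 carried a date in place of a symbol in the files. Entries without a name in the files took between 4.74% and 11.41% of the counts of a library. The recovery tables list 64235 entries without counts or depths, so the depth behind an FPKM is unknown, and 16342 gene identifiers stand in both experiments. Positions are those of GENCODE 29 on GRCh38.

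Counts were normalised by TMM and fitted with edgeR's quasi-likelihood model over all 18 libraries (edgeR 4.0.16 under R 4.3.3). The filter filterByExpr kept all 16430 genes. FPKM values were fitted with limma 3.58.1 (limma-trend) on log2(FPKM + 1) over all 8 libraries, for the 18098 genes at 1 FPKM or more in at least 2 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Log2 fold changes are given with their standard error. Levels are CPM (counts scaled to library size, after TMM) or FPKM, as the mean ± SD of a group of 3 or as the separate values of a group of 2. For a gene without counts in a whole group, the fold is a bound from a floor of 3 counts over the group, which covers counting error only. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so single genes rest on the models.

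In the drug experiment the comparisons were dexamethasone, quizartinib and the combination against DMSO at 48 h, the combination against quizartinib at 48 h and at 5 days, quizartinib at 5 days against DMSO and against quizartinib at 48 h, and a pair of differences between effects. The first, called the interaction, is the effect of dexamethasone with quizartinib minus its effect without quizartinib at 48 h. The second is the effect of dexamethasone with quizartinib at 5 days minus that at 48 h. In the recovery experiment they were survivors, 13 days and 30 days against untreated cells, 13 days against survivors, and 30 days against 13 days. These comparisons, the tests, the gene lists and the rule for naming genes were set before the data were examined.

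The 27 gene lists were glucocorticoid receptor targets, inflammatory and NF-kB genes, interferon-stimulated genes, adhesion and migration genes, FLT3-STAT5-MAPK output genes, cell cycle genes, MYC targets and ribosome biogenesis, the pro-apoptotic and the anti-apoptotic BCL2 family, monocyte and macrophage genes, granule genes of myeloid progenitors, stem and progenitor genes, sterol and lipid synthesis, glycolysis, oxidative phosphorylation, ATF4 and amino acid response, lysosome and autophagy, MHC class II, MHC class I, FOXO and quiescence genes, p53 targets, mitochondrially encoded genes, ribosomal protein genes, and markers of erythroid cells and megakaryocytes, T and NK cells, B cells, and fibroblasts and epithelium. Of these, 26 had at least 2 measured genes in the drug experiment and 24 in the recovery experiment, where the erythroid, the T and NK cell and the fibroblast markers had fewer. Each was tested with camera of limma at a preset correlation of 0.01, on log2 CPM with a prior count of 2 or on log2(FPKM + 1), with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Of 354 list results, camera called 139 at the preset correlation and 7 with the estimated correlation. Where only the first holds, the adjusted p with the estimated correlation is given. Counts of called list members are given over all genes tested and, in brackets, adjusted over the list alone.

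The named genes are FLT3, NR3C1 (the glucocorticoid receptor), BCL2L11 and MCL1 in every comparison. Next come the 6 highest and the 6 lowest log2 fold changes among called genes whose replicate values do not overlap between the groups and whose mean over all libraries is at least 5 CPM or 2 FPKM. Of each list described, up to 4 called members with the largest changes and up to 2 members that were not called are named. The lists described are the glucocorticoid receptor targets, the FLT3 output genes, the inflammatory genes, both BCL2 family lists, and any list with a camera adjusted p under 0.05. A gene named in one comparison may be followed in the others. In the recovery experiment the highest and lowest genes were largely short noncoding RNAs, so the protein-coding genes highest and lowest by the same rule were added after the values had been seen. Genes outside the rule are marked where they appear.

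Genes called in quizartinib against DMSO at 48 h and changed at least 2-fold were carried over to the recovery experiment as separate lists of higher and lower genes. The experiments share no library. Overlaps and correlations of fold changes across genes were computed only for comparisons that share no library.

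Equal replicate numbers may pair libraries across groups. This was checked by correlating, across genes, each library's deviation from its group mean between groups. The numbers were taken as pairs where every correlation of equal numbers was above 0.1. This held for dexamethasone against DMSO (0.2533 to 0.6353), quizartinib against DMSO at 48 h (0.1002 to 0.2679) and the combination against quizartinib at 48 h (0.1236 to 0.2709). The labels do not state a pairing, and the pairing comes from these correlations alone. The fits reported use no block, and the blocked fit is an alternative.

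The alternatives planned for the drug experiment were DESeq2 1.42.0 with its size factors, no filter, a block for the replicate number, a fit of only the groups compared, and each library left out in turn. No filter changed nothing there, since the filter had kept every gene. A planned change of pseudocount does not apply to counts. For the recovery experiment the alternatives were a pseudocount of 0.1, no filter, quantile normalisation, the block, a fit of only the groups compared, and each library left out in turn. Where that left a group with 1 library, the fit pools the spread, and the lone library is assumed to vary like the other groups. For the carried-over genes, lists with no minimum fold and lists without cell cycle members were run. Alternatives chosen after seeing the data left out the 4 libraries numbered 3 of the 48 h groups, kept only protein-coding genes of the recovery experiment, and divided FPKM values by the sum over genes that are not mitochondrially encoded.

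The fits were tested on simulated data with 50 genes changed per fold. Real data had far more calls, so the rates below may not hold. At 1.5-fold, 2-fold, 4-fold and 8-fold, edgeR recovered 48%, 76%, 100% and 100% of the genes for quizartinib against DMSO at 48 h, and 50%, 80%, 100% and 100% for the combination against quizartinib. Of the 15985 genes in each, 6 and 4 unchanged genes were called. For survivors against untreated cells limma recovered 10%, 32%, 100% and 100%, with 5 unchanged genes of 18098 called. All value columns were used.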

Results

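RNA of MV4-11 cells was sequenced in a drug experiment of 18 libraries and a recovery experiment of 8 libraries. The drug experiment held 3 libraries each of DMSO, dexamethasone, quizartinib and their combination at 48 h, and of quizartinib and the combination at 5 days. The recovery experiment held 2 libraries each of untreated cells, cells that survived 48 h in 100 nM quizartinib, and survivors after 13 and 30 days in drug-free medium. Total counts of the drug experiment were 21597617, 21263794 and 23641880 for DMSO, 22905870, 17814188 and 22787090 for dexamethasone, 18773768, 18437559 and 23243740 for quizartinib at 48 h, and 24990476, 23424123 and 21577884 for the combination at 48 h. They were 17693984, 18608880 and 18197527 for quizartinib and 14945136, 14795190 and 21325569 for the combination at 5 days. The recovery experiment was deposited as FPKM, and the depth behind these values is unknown.

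Quizartinib separated the drug libraries most, and the first principal component held 65.3% of their variance. The small noncoding RNAs 7SK and 7SL took 10.95% ± 1.27 of the counts in DMSO, 10.91% ± 1.02 in dexamethasone, 17.3% ± 1.39 in quizartinib and 25.04% ± 5.69 in the combination at 48 h (SD, n = 3 each). Their share was 31.6% in the third combination library of 48 h. At 5 days it was 19.99% ± 1.30 with quizartinib and 18.64% ± 3.03 with the combination (SD, n = 3 each). Libraries numbered 3 of the 48 h groups stood apart on principal component 3 (-39.05 against 23.43 and 21.84 in DMSO) and in single genes. FOS was at 49.87, 50.27 and 925.8 CPM in DMSO replicates 1, 2 and 3. EGR1 was at 28.36, 40.91 and 426.9 CPM, and DUSP1, a glucocorticoid receptor target, at 1.87, 1.73 and 196.8 CPM there. MCL1, an anti-apoptotic BCL2 relative, was at 190.4, 203.1 and 525.8 CPM in DMSO and 178.2, 183.3 and 750.3 CPM in quizartinib at 48 h.

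Dexamethasone against DMSO at 48 h asks what the glucocorticoid does alone. BCL2L11, which encodes the pro-apoptotic protein BIM (chromosome 2, 111119378 to 111168447), rose from 31.15 ± 4.53 to 87.46 ± 7.81 CPM (SD, n = 3 each), a log2 fold change of 1.49 ± 0.14 (edgeR adjusted p = 8.2e-07). BCL2, its anti-apoptotic relative (chromosome 18, 63123346 to 63320128), fell from 279.9 ± 15.2 to 142.9 ± 39.8 CPM (log2 fold change -0.97 ± 0.15, edgeR adjusted p = 0.00035). FKBP5, an immunophilin and classical target of the receptor, rose from 103.9 ± 7.48 to 1461 ± 54.9 CPM (3.81 ± 0.09, adjusted p = 8.2e-15). MPEG1, a macrophage pore-forming protein, fell from 64.2 ± 7.24 to 3.15 ± 1.73 CPM (-4.38 ± 0.29), and HLA-DRA, an MHC class II chain, from 15.28 ± 4.15 to 3.41 ± 0.91 CPM (-2.16 ± 0.27).

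The 6 highest genes were CYP19A1, THBS1, GSTM3, MFGE8, ADAMTS2 and ZBTB16. CYP19A1, the oestrogen-forming aromatase, had no counts in DMSO and 36.65 ± 27.92 CPM with dexamethasone, at least 831-fold higher against a floor of 3 counts over the group. ADAMTS2, a procollagen protease (chromosome 5, 179110851 to 179345430), rose from 2.17 ± 0.28 to 71.03 ± 8.73 CPM (5.03 ± 0.16), GSTM3 by 6.24 ± 0.37 and MFGE8 by 6.14 ± 0.42. The lowest after MPEG1 were ENPP2 (-3.86), DTX4 (-3.59), CD84 (-3.48), COL24A1 (-3.45) and SLC4A3 (-3.34). Of 20 glucocorticoid receptor targets 11 rose (14 adjusted over the list alone, median 1.38, camera adjusted p = 1.78e-16, and adjusted p = 0.349 with an estimated correlation), among them CD163, a scavenger receptor (9.00 ± 0.85), ZBTB16 (4.84 ± 0.44) and ERRFI1 (3.26 ± 0.50). DUSP1 was not called (1.14 ± 1.36, adjusted p = 0.68). Of 10 MHC class II genes 8 fell (8 adjusted over the list alone, median -1.24, camera adjusted p = 7.57e-07, and adjusted p = 0.349 with an estimated correlation). Of 12 MHC class I genes 2 fell (3 adjusted over the list alone, median -0.23, camera adjusted p = 0.00484, and adjusted p = 0.352 with an estimated correlation), PSMB9 among them (-0.9965 ± 0.1441).

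Among 25 output genes of FLT3, STAT5 and MAPK signalling 6 rose with dexamethasone (6 adjusted over the list alone, median 0.19, camera adjusted p = 0.000779, and adjusted p = 0.401 with an estimated correlation), such as the feedback inhibitors SOCS1 (3.27 ± 0.36) and SPRY2 (1.90 ± 0.32), IL2RA (1.76 ± 0.30) and ETV4 (1.33 ± 0.25). Of 16 inflammatory and NF-kB genes 4 rose (6 adjusted over the list alone, median 0.57, camera adjusted p = 0.00211, and adjusted p = 0.401 with an estimated correlation). NFKBIA, which encodes the inhibitor of NF-kB, was among them (1.37 ± 0.20). Of 17 FOXO and quiescence genes 3 rose, PIK3IP1 (3.43 ± 0.17), IRS2 (2.28 ± 0.35) and FOXO3 (0.75 ± 0.11), or 4 adjusted over the list alone (median 0.19, camera adjusted p = 0.00118, and adjusted p = 0.352 with an estimated correlation). Of 16 amino acid and ATF4 response genes 7 rose, such as TRIB3 (1.83 ± 0.42) and ASNS (0.49 ± 0.08), or 10 adjusted over the list alone (median 0.39, camera adjusted p = 9.85e-06, and adjusted p = 0.352 with an estimated correlation). DDIT4 of this list rose too (2.81 ± 0.59) and was at 8.997, 10.67 and 46.63 CPM in DMSO and 64.25, 65.45 and 334.4 CPM in dexamethasone replicates 1, 2 and 3. Of 18 adhesion and migration genes 6 fell and 1 rose (6 and 2 adjusted over the list alone, median -0.17, camera adjusted p = 0.00964, and adjusted p = 0.401 with an estimated correlation), with ITGB7 (-2.33 ± 0.16) and CD44 (-1.46 ± 0.11) among the lower. Camera also called the sterol and lipid synthesis genes (median 0.45, 1 member higher, adjusted p = 0.00158, and adjusted p = 0.749 with an estimated correlation) and the mitochondrially encoded genes (median 0.25, adjusted p = 0.032, and adjusted p = 0.752 with an estimated correlation). Without the libraries numbered 3 of the 48 h groups the mitochondrially encoded genes were not called (adjusted p = 0.0784).

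Of 16430 genes, edgeR called 904 higher and 1089 lower with dexamethasone, of which 339 and 296 changed at least 2-fold. FLT3 (0.24 ± 0.08, adjusted p = 0.081), NR3C1 (0.28 ± 0.09, adjusted p = 0.053) and MCL1 (0.22 ± 0.54, adjusted p = 0.86) were not called. With only the DMSO and dexamethasone libraries in the fit, 579 genes were called. With a block for the replicate number NR3C1 was called.

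**Figure D1:**
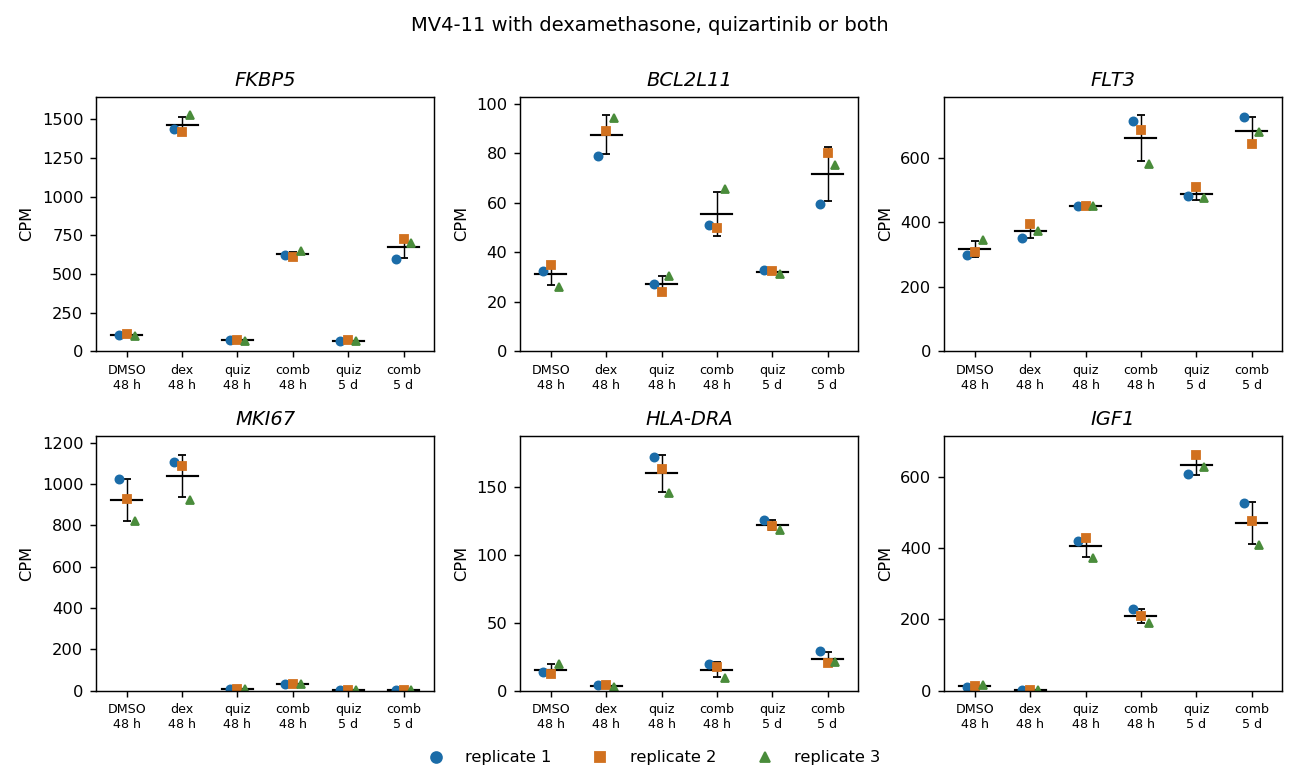
Levels in CPM of FKBP5, BCL2L11, FLT3, MKI67, HLA-DRA and IGF1 in each of the 18 libraries of the drug experiment, by group. Points are libraries, the black line is the mean and the bars are the SD of 3 libraries, and BCL2L11 has means of 31.15 CPM in DMSO, 87.46 with dexamethasone, 27.29 with quizartinib and 55.42 with the combination at 48 h.

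Quizartinib against DMSO at 48 h asks what FLT3 inhibition does. MKI67, a marker of proliferation, fell from 923.8 ± 101.3 to 6.39 ± 1.71 CPM (SD, n = 3 each), a log2 fold change of -7.17 ± 0.19 (edgeR adjusted p = 1.2e-14). IGF1, a growth factor, rose from 13.8 ± 2.79 to 406.8 ± 30.9 CPM (4.88 ± 0.15, adjusted p = 5.0e-14). BMF, a pro-apoptotic BCL2 relative (chromosome 15, 40087890 to 40108892), rose from 32.34 ± 1.13 to 150.9 ± 6.62 CPM (2.22 ± 0.08, adjusted p = 1.9e-13), while BAX fell by 0.77 ± 0.09 and BCL2 by 0.63 ± 0.15. The target itself, FLT3, rose from 317 ± 23.9 to 450.3 ± 0.39 CPM (0.51 ± 0.08, adjusted p = 6.1e-05), and NR3C1 fell from 158.1 ± 8.46 to 125.5 ± 13.4 CPM (-0.33 ± 0.09, adjusted p = 0.0049). BCL2L11 (-0.19 ± 0.14, adjusted p = 0.24) and MCL1 (0.27 ± 0.54, adjusted p = 0.68) were not called.

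All 23 cell cycle genes fell (23 adjusted over the list alone, median -5.0033, camera adjusted p = 8.01e-20), and this call held with an estimated correlation (adjusted p = 0.0104). The lowest genes were E2F8 (-9.50 ± 0.44), CDC45 (-8.91 ± 0.32), E2F2 (-8.64), MYBL2 (-8.55 ± 0.27), KIF18B (-8.53) and PBK (-8.51), and RRM2, which makes deoxynucleotides, fell by 7.51 ± 0.26. Of 25 FLT3 output genes 16 fell (16 adjusted over the list alone, median -1.38, camera adjusted p = 3.16e-05, and adjusted p = 0.380 with an estimated correlation). ETV4, a MAPK-driven transcription factor, went from 3.56 ± 0.51 CPM to no counts, at least 72.4-fold lower, and CCND1 (-5.94 ± 0.80) and ETV5 (-3.83 ± 0.41) fell. All 17 MYC targets and ribosome biogenesis genes fell (17 adjusted over the list alone, median -1.21, camera adjusted p = 2.49e-07, and adjusted p = 0.265 with an estimated correlation), with NCL at -1.50 ± 0.16. All 18 sterol and lipid synthesis genes fell (18 adjusted over the list alone, median -2.36, camera adjusted p = 4.03e-07, and adjusted p = 0.434 with an estimated correlation), DHCR7 by 7.14 ± 0.60. All 15 glycolysis genes fell (15 adjusted over the list alone, median -1.35, camera adjusted p = 1.13e-05, and adjusted p = 0.434 with an estimated correlation), LDHA by 2.44 ± 0.24. Of 15 oxidative phosphorylation genes 12 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.57, camera adjusted p = 0.00138, and adjusted p = 0.434 with an estimated correlation), CYCS by 1.36 ± 0.12. Of 16 ATF4 response genes 11 fell and 2 rose (median -0.68, camera adjusted p = 0.00138, and adjusted p = 0.434 with an estimated correlation), and the serine synthesis enzymes PHGDH and PSAT1 fell by 6.51 ± 0.24 and 3.64 ± 0.10.

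All 10 MHC class II genes rose with quizartinib (10 adjusted over the list alone, median 3.10, camera adjusted p = 9.45e-07, and adjusted p = 0.265 with an estimated correlation). HLA-DPA1 rose from 2.72 ± 1.10 to 35.42 ± 6.60 CPM (3.69 ± 0.31) and HLA-DPB1 by 4.15 ± 0.36. Of 18 interferon-stimulated genes 11 rose (11 adjusted over the list alone, median 0.86, camera adjusted p = 0.00671, and adjusted p = 0.350 with an estimated correlation), such as RSAD2 (2.60 ± 0.22) and DDX58 (1.54 ± 0.13). Of 18 adhesion genes 11 rose and 2 fell (median 0.84, camera adjusted p = 0.0363, and adjusted p = 0.501 with an estimated correlation), with the integrins ITGAX (2.41 ± 0.41) and ITGB7 (2.24 ± 0.14) among the higher. Of 20 lysosome and autophagy genes 10 rose and 2 fell (median 0.43, camera adjusted p = 0.0358, and adjusted p = 0.265 with an estimated correlation), with GABARAPL1 at 2.13 ± 0.16, and without the libraries numbered 3 this list was not called (adjusted p = 0.0597). Of 17 FOXO and quiescence genes 9 rose and 2 fell (median 0.45, camera adjusted p = 0.0261, and adjusted p = 0.464 with an estimated correlation), with the cell cycle inhibitor CDKN1C at 3.45 ± 0.22. The glucocorticoid receptor targets went both ways, with 4 higher and 5 lower of 20 (median -0.23, camera adjusted p = 0.996). PDK4 rose by 3.35 ± 0.52 and MT2A fell by 2.56 ± 0.26. Monocyte and macrophage genes missed the threshold (7 higher and 3 lower of 16, median 0.49, camera adjusted p = 0.0897) and passed it without the libraries numbered 3 (adjusted p = 0.0399).

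Other lists were not called by camera in this comparison. The median was -0.20 for the 9 pro-apoptotic BCL2 family genes (adjusted p = 0.787), -0.05 for the 4 anti-apoptotic ones (adjusted p = 0.729), 0.28 for the 10 stem and progenitor genes (adjusted p = 0.438) and -0.35 for the 11 p53 targets, of which 7 fell and 2 rose (adjusted p = 0.524). It was -0.16 for the 6 B cell markers (adjusted p = 0.951), 1.60 for the 2 T and NK cell markers (adjusted p = 0.458), 0.91 for the 3 fibroblast and epithelial markers, where the test pointed the same way (adjusted p = 0.879), and 0.22 for the 19 ribosomal protein genes, of which 8 rose (adjusted p = 0.0773). With the replicate block the ribosomal protein genes were called (adjusted p = 0.032). ITGA2B was the only erythroid or megakaryocyte marker measured, so that list was not tested.

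EdgeR called 4770 genes higher and 4994 lower with quizartinib at 48 h, of which 2157 and 1992 changed at least 2-fold. The shares of 7SK and 7SL rose along with these lists, from 10.95% to 17.3% of the counts.

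**Figure D2:**
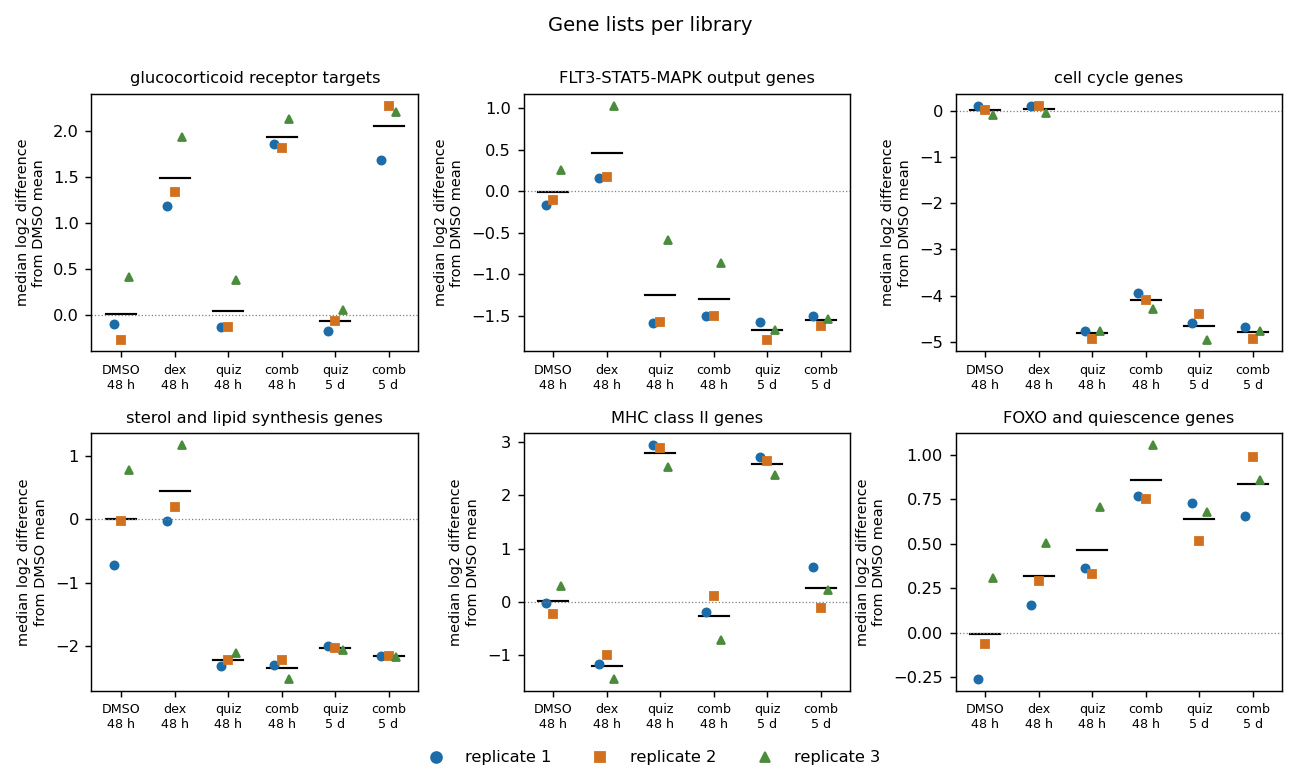
Median over the genes of a list of the log2 CPM difference from the mean of the DMSO libraries, for each of the 18 libraries by group. Points are libraries and lines are the mean of 3, and with quizartinib at 48 h the fitted list medians were -5.0033 for cell cycle genes and 3.10 for MHC class II genes.

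The combination against quizartinib at 48 h asks what dexamethasone adds to FLT3 inhibition. BCL2L11 rose from 27.29 ± 3.16 to 55.42 ± 8.86 CPM (SD, n = 3 each), a log2 fold change of 1.02 ± 0.14 (edgeR adjusted p = 6.6e-05). FLT3 rose from 450.3 ± 0.39 to 661.2 ± 70.7 CPM (0.55 ± 0.08, adjusted p = 0.00025). MHC class II mRNAs fell. HLA-DRA went from 160.3 ± 13.5 to 15.49 ± 5.45 CPM (-3.36 ± 0.24, adjusted p = 5.6e-08), and CIITA, the transactivator of these genes, from 94.4 ± 18.3 to 13.57 ± 1.90 CPM (-2.80 ± 0.22). FKBP5 rose from 70.41 ± 1.83 to 627 ± 16.6 CPM (3.15 ± 0.08, adjusted p = 1.3e-13). MKI67 was higher than with quizartinib alone, at 32.36 ± 0.98 against 6.39 ± 1.71 CPM (2.33 ± 0.17, adjusted p = 5.6e-08), and below its 923.8 CPM in DMSO.

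All 10 MHC class II genes fell (10 adjusted over the list alone, median -3.41, camera adjusted p = 4.92e-24), and this call held with an estimated correlation (adjusted p = 0.0103). Of 12 MHC class I genes 6 fell (8 adjusted over the list alone, median -0.40, camera adjusted p = 0.000396, and adjusted p = 0.155 with an estimated correlation), such as PSMB9 (-0.67 ± 0.15) and TAPBP (-0.49 ± 0.08). Of 20 glucocorticoid receptor targets 13 rose (14 adjusted over the list alone, median 1.52, camera adjusted p = 6.99e-15, and adjusted p = 0.155 with an estimated correlation), among them ZBTB16 (5.80 ± 0.49), TSC22D3 (2.89 ± 0.54) and CD163, which had no counts with quizartinib and was at least 27.7-fold higher. Of 23 cell cycle genes 11 rose (13 adjusted over the list alone, median 0.38, camera adjusted p = 7.39e-06, and adjusted p = 0.155 with an estimated correlation), such as CDC20 (1.84 ± 0.31), RRM2 (1.73 ± 0.27) and AURKB (1.61 ± 0.25). Of 18 adhesion genes 6 fell and 1 rose (6 and 2 adjusted over the list alone, median -0.49, camera adjusted p = 0.000412, and adjusted p = 0.226 with an estimated correlation), with the integrin ITGAL (-1.32 ± 0.12) among the lower. Of 17 FOXO and quiescence genes 7 rose (7 adjusted over the list alone, where 1 more fell, median 0.55, camera adjusted p = 0.000412, and adjusted p = 0.226 with an estimated correlation), PIK3IP1 by 2.68 ± 0.15 and IRS2 by 2.06 ± 0.35. Of the 3 fibroblast and epithelial markers 2 rose (3 adjusted over the list alone, median 0.77, camera adjusted p = 0.0036, and adjusted p = 0.155 with an estimated correlation), KRT18 by 0.77 ± 0.17, a keratin. The FLT3 output list was not called (median -0.04, camera adjusted p = 0.409), although SOCS1 (2.56 ± 0.36) and CCND3 (0.71 ± 0.10) rose. In the inflammatory list IL18 (1.15 ± 0.13) and NFKBIA (0.90 ± 0.20) rose.

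The highest genes were MFGE8 (8.01 ± 0.55), GSTM3 (7.99 ± 0.39), CYP19A1 (7.41 ± 0.92), ZBTB16, ADAMTS2 (5.27 ± 0.16) and THBS1 (5.07 ± 0.91), and MPEG1 fell by 2.84 ± 0.25. EdgeR called 924 genes higher and 761 lower, of which 408 and 201 changed at least 2-fold. BCL2 fell from 180.6 ± 15.2 to 112.5 ± 12.5 CPM (-0.68 ± 0.15, adjusted p = 0.0073), NR3C1 (0.02 ± 0.09, adjusted p = 0.94) and MCL1 (-0.48 ± 0.54, adjusted p = 0.70) were not called. Without the third combination library BCL2 was at -0.59 and no longer called (adjusted p = 0.0501).

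The combination against DMSO at 48 h gives the summed change. BCL2L11 was at 55.42 against 31.15 CPM (0.83 ± 0.13, edgeR adjusted p = 4.0e-05), BMF at 159.4 against 32.34 CPM (2.30 ± 0.08) and BCL2 at 112.5 against 279.9 CPM (-1.31 ± 0.16, adjusted p = 1.2e-06). FLT3 rose to 661.2 ± 70.7 CPM (1.06 ± 0.09, adjusted p = 9.9e-09), NR3C1 fell (-0.31 ± 0.09, adjusted p = 0.0067), BAX fell (-0.88 ± 0.09) and MCL1 was not called (-0.20 ± 0.54, adjusted p = 0.76). GSTM3 (7.49 ± 0.36), TNK2-AS1 (6.30 ± 0.29) and ADAMTS2 (6.25 ± 0.17) were among the highest, and CYP19A1 was at least 84.4-fold higher. PHGDH (-7.64 ± 0.27), CDC45 (-7.00 ± 0.27) and DHCR7 (-6.92 ± 0.58) were among the lowest.

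Of 20 glucocorticoid receptor targets 14 rose and 2 fell (14 and 2 adjusted over the list alone, median 1.76, camera adjusted p = 0.000659, and adjusted p = 0.546 with an estimated correlation), PDK4 by 5.56 ± 0.46 and MERTK by 4.14 ± 0.37. All 23 cell cycle genes were lower than in DMSO (median -4.21, camera adjusted p = 2.22e-17), and this held with an estimated correlation (adjusted p = 0.0178). Ribosomal protein genes were called higher (10 of 19, or 6 adjusted over the list alone, median 0.23, camera adjusted p = 0.0469, and adjusted p = 0.822 with an estimated correlation), RPL13 by 0.56 ± 0.12. Camera also called MYC target (median -1.40), glycolysis (-1.58), FLT3 output (-1.52), oxidative phosphorylation (-0.68) and ATF4 response genes (-0.72) lower and interferon-stimulated genes (0.70) higher, with adjusted p = 0.484, 0.484, 0.484, 0.487, 0.497 and 0.484 with an estimated correlation, in that order. It called sterol genes (median -2.62, camera adjusted p = 4.77e-07, and adjusted p = 0.484 with an estimated correlation) and FOXO and quiescence genes (11 of 17 higher, median 0.59, camera adjusted p = 0.000659, and adjusted p = 0.484 with an estimated correlation), PIK3IP1 by 4.82 ± 0.17. MHC class II genes were not called (2 higher and 4 lower of 10, median -0.42, camera adjusted p = 0.802). EdgeR called 5138 genes higher and 5224 lower.

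At 5 days quizartinib against DMSO of 48 h asks what longer FLT3 inhibition does, and the time in culture differs along with the drug. IGF1 stood at 633.2 ± 27.4 CPM (SD, n = 3), a log2 fold change of 5.52 ± 0.15 (edgeR adjusted p = 1.4e-14), and MKI67 at 1.11 ± 0.20 CPM (-9.69 ± 0.23). CDC45, a part of the replicative helicase, had no counts at 5 days and was at least 789-fold lower. BMF stayed higher (140.6 ± 14.0 CPM, 2.12 ± 0.08), BAX (-1.01 ± 0.09) and BCL2 (-0.61 ± 0.15) were lower, FLT3 higher (488.7 ± 17.7 CPM, 0.62 ± 0.08, adjusted p = 5.6e-06) and NR3C1 lower (-0.39 ± 0.09, adjusted p = 0.0013). BCL2L11 (0.05 ± 0.14, adjusted p = 0.77) and MCL1 (0.43 ± 0.54, adjusted p = 0.50) were not called.

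All 23 cell cycle genes were lower (median -4.71, camera adjusted p = 2.11e-18), and this held with an estimated correlation (adjusted p = 0.0142). All 10 MHC class II genes were higher (median 2.94, camera adjusted p = 1.19e-05) and all 17 MYC targets lower (median -1.43, camera adjusted p = 1.15e-07), with adjusted p = 0.315 for each with an estimated correlation. Of 25 FLT3 output genes 20 fell (median -1.68, camera adjusted p = 2.64e-05) and all 18 sterol genes fell (median -2.21, camera adjusted p = 3.70e-06), FASN by 3.14 ± 0.12, each with adjusted p = 0.425 with an estimated correlation. Camera also called glycolysis (median -1.48), oxidative phosphorylation (-0.88) and ATF4 response genes (-1.15) lower and interferon-stimulated (0.47) and FOXO genes (0.54) higher, each with adjusted p = 0.425 with an estimated correlation, and lysosome genes higher (0.23, and adjusted p = 0.315 with an estimated correlation). EdgeR called 5045 genes higher and 5268 lower.

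Quizartinib at 5 days against 48 h showed smaller changes, and the third quizartinib library of 48 h is among those that stand apart. Ribosomal protein mRNAs fell, RPS2 from 2843 ± 382 to 1774 ± 113 CPM (SD, n = 3 each), a log2 fold change of -0.68 ± 0.11 (edgeR adjusted p = 0.0028), and RPL5 by 0.66 ± 0.10. Of 19 such genes 12 fell (19 adjusted over the list alone, median -0.52, camera adjusted p = 1.97e-17, and adjusted p = 0.468 with an estimated correlation). MKI67 fell further (-2.52 ± 0.22, adjusted p = 1.3e-05), as did PCLAF (-3.73 ± 0.33), a replication clamp partner, and TYMS (-3.05 ± 0.42). CDKN1A, the p53-responsive cell cycle inhibitor p21, fell from 20.11 ± 1.45 to 4.38 ± 0.57 CPM (-2.20 ± 0.34, adjusted p = 0.0020). Of 11 p53 targets 3 fell (5 adjusted over the list alone, median -0.32, camera adjusted p = 0.00016, and adjusted p = 0.156 with an estimated correlation), TNFRSF10B by 0.63 ± 0.10. ALDH1L2, a mitochondrial folate enzyme, rose by 1.38 ± 0.14 and AZU1, a granule protein, by 0.50 ± 0.07.

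Of 17 MYC targets 2 fell (3 adjusted over the list alone, median -0.13, camera adjusted p = 0.00513, and adjusted p = 0.728 with an estimated correlation), NPM1 by 0.56 ± 0.08, and this list was not called without the libraries numbered 3 (adjusted p = 0.0961). Of 15 oxidative phosphorylation genes 2 fell (7 adjusted over the list alone, median -0.22, camera adjusted p = 0.000101, and adjusted p = 0.604 with an estimated correlation). Camera also called the granule genes (median 0.25) and mitochondrially encoded genes (median 0.25) higher and the MHC class I (median -0.29) and MHC class II genes (median -0.40) lower, with adjusted p = 0.0131, 0.0126, 0.0129 and 0.0334, and adjusted p = 0.728, 0.732, 0.604 and 0.732 with an estimated correlation, in that order. EdgeR called 146 genes higher and 374 lower. Leaving out 1 library gave between 133 and 370 called genes, with 244, 370 and 182 without the 48 h replicates 1, 2 and 3 and 235, 133 and 234 without those of 5 days, and 1068 genes were called without the libraries numbered 3. FLT3 (0.12 ± 0.08, adjusted p = 0.52), BCL2L11 (0.24 ± 0.14, adjusted p = 0.40), NR3C1 (-0.06 ± 0.09, adjusted p = 0.80) and MCL1 (0.16 ± 0.54, adjusted p = 0.92) were not called.

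The combination against quizartinib at 5 days asks what dexamethasone does when it is added on day 3. BCL2L11 rose from 32.21 ± 0.90 to 71.59 ± 10.9 CPM (SD, n = 3 each), a log2 fold change of 1.15 ± 0.14 (edgeR adjusted p = 1.9e-05), and FLT3 from 488.7 ± 17.7 to 684.1 ± 43.1 CPM (0.49 ± 0.08, adjusted p = 0.0011). HLA-DRA fell from 121.9 ± 3.70 to 23.58 ± 4.98 CPM (-2.37 ± 0.23) and CD74, the class II invariant chain (chromosome 5, 150401637 to 150412929), by 2.32 ± 0.16. FKBP5 rose from 69.00 ± 1.58 to 674.1 ± 68.2 CPM (3.29 ± 0.08, adjusted p = 7.1e-14), and GSTM3 (7.03 ± 0.36), MFGE8 (6.93 ± 0.55), CYP19A1 (6.81 ± 0.83) and ADAMTS2 (5.07 ± 0.16) were again the highest.

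All 10 MHC class II genes fell (10 adjusted over the list alone, median -2.54, camera adjusted p = 3.85e-19), and this held with an estimated correlation (adjusted p = 0.0257). Of 20 glucocorticoid receptor targets 12 rose (12 adjusted over the list alone, median 1.43, camera adjusted p = 4.17e-14, and adjusted p = 0.344 with an estimated correlation), MERTK by 2.75 ± 0.32 and ZBTB16 by 4.90 ± 0.47. Of 17 FOXO genes 6 rose (median 0.33, camera adjusted p = 0.000859, and adjusted p = 0.454 with an estimated correlation), PIK3IP1 by 2.54 ± 0.15. Of 12 MHC class I genes 3 fell (4 adjusted over the list alone, median -0.20, camera adjusted p = 0.00783, and adjusted p = 0.454 with an estimated correlation). Of 18 adhesion genes 3 fell and 1 rose (6 and 1 adjusted over the list alone, median -0.36, camera adjusted p = 0.0138, and adjusted p = 0.525 with an estimated correlation), with ITGAL at -1.60 ± 0.12 and the chemokine receptor CXCR4 at 0.56 ± 0.11. The cell cycle list was not called (median -0.07, camera adjusted p = 0.332). SOCS1 (2.10 ± 0.38), CCND3 (0.73 ± 0.10), IL18 (1.32 ± 0.13) and NFKBIA (1.12 ± 0.20) rose. EdgeR called 755 genes higher and 664 lower. Leaving out 1 library gave between 818 and 1217 genes, 835 without quizartinib replicate 1, 818 without combination replicate 2 and 940 without combination replicate 3, and 2758 were called without the libraries numbered 3. NR3C1 (0.20 ± 0.09, adjusted p = 0.22) and MCL1 (-0.06 ± 0.54, adjusted p = 0.98) were not called, and the call of BCL2 (-0.53 ± 0.15, adjusted p = 0.041) was lost when any of 5 of the 6 libraries was left out.

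The interaction at 48 h asks whether dexamethasone acts differently with and without quizartinib. TLR4, the endotoxin receptor, went from 14.37 ± 1.06 to 129.5 ± 7.41 CPM with dexamethasone alone and from 17.98 ± 2.82 to 21.59 ± 1.83 CPM with quizartinib present (SD, n = 3 each), an interaction of -2.91 ± 0.21 (edgeR adjusted p = 1.5e-06). SLC7A11, the cystine transporter, went from 9.56 ± 1.71 to 14.94 ± 3.05 CPM without quizartinib and from 17.03 to 3.54 CPM with it (-2.91 ± 0.25, adjusted p = 9.4e-06). CHAC1, a glutathione-degrading ATF4 target, went from 10.53 ± 2.40 to 14.89 ± 1.91 CPM without and from 2.21 to 11.35 CPM with quizartinib (1.85 ± 0.26, adjusted p = 0.00098). FKBP5 rose less with quizartinib present (-0.66 ± 0.11, adjusted p = 0.0033). MKI67 was higher relative to the dexamethasone effect alone (2.16 ± 0.22, adjusted p = 4.6e-05), as were UBE2C (3.08 ± 0.47) and HJURP (2.72 ± 0.38). BCL2L11 (-0.47 ± 0.19, adjusted p = 0.26), FLT3 (0.32 ± 0.12, adjusted p = 0.22), NR3C1 (-0.26 ± 0.13, adjusted p = 0.40) and MCL1 (-0.69 ± 0.76, adjusted p = 0.76) were not called.

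Of 10 MHC class II genes 6 were lower (8 adjusted over the list alone, median -1.36, camera adjusted p = 1.10e-16), and this held with an estimated correlation (adjusted p = 0.0431), with CIITA at -1.50 ± 0.31 and CD74 at -1.14 ± 0.22. Of 23 cell cycle genes 7 were higher (10 adjusted over the list alone, median 0.60, camera adjusted p = 9.82e-05, and adjusted p = 0.354 with an estimated correlation). Of 16 monocyte and macrophage genes 1 was lower (4 adjusted over the list alone, median -0.35, camera adjusted p = 0.000182, and adjusted p = 0.612 with an estimated correlation). Of 20 glucocorticoid receptor targets 1 was lower (3 adjusted over the list alone, median -0.27, camera adjusted p = 0.0431, and adjusted p = 0.644 with an estimated correlation). Camera alone called the sterol genes (median -0.69, adjusted p = 0.00013) and the glycolysis genes (median -0.33, adjusted p = 0.0222), each with adjusted p = 0.644 with an estimated correlation. The other 5 lists called here (FLT3 output, granule, ATF4 response, mitochondrially encoded and lysosome genes) were not called without the libraries numbered 3, where their adjusted p were 0.377, 0.177, 0.162, 0.162 and 0.162 in that order. With all libraries they had adjusted p = 0.644, 0.644, 0.644, 0.644 and 0.254 with an estimated correlation. EdgeR called 244 genes higher and 123 lower. Fewer were called with only the 4 groups in the fit (189) and more with DESeq2 (597) or the replicate block (572), and leaving out 1 library gave between 218 and 414.

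The effect of dexamethasone at 5 days minus that at 48 h, both with quizartinib, was called by edgeR for 8 genes, and 638 had an unadjusted p under 0.05. The 8 were lower at 5 days and included IQGAP3 (-3.12 ± 0.42, adjusted p = 0.0036), CENPF (-1.62 ± 0.21, adjusted p = 0.0036) and CCNB2 (-1.45 ± 0.19, adjusted p = 0.0036), which act in mitosis and cell division. MKI67 (-2.11 ± 0.33, adjusted p = 0.020), CDCA5 (-2.74 ± 0.41) and TOP2A (-1.52 ± 0.24) were called as well, but not in every fit with 1 library left out. Of 23 cell cycle genes 3 were lower (8 adjusted over the list alone, median -0.37, camera adjusted p = 4.01e-14), and this held with an estimated correlation (adjusted p = 0.0395). Camera alone called the MHC class II genes (median 0.57, 4 higher adjusted over the list alone, adjusted p = 3.83e-07, and adjusted p = 0.315 with an estimated correlation). BCL2L11 (0.13 ± 0.19) and FLT3 (-0.07 ± 0.12) were not called (adjusted p = 1 for each), and neither were NR3C1 (0.18 ± 0.13) and MCL1 (0.41 ± 0.76). DESeq2 called 39 genes, the replicate block 19, the fit of only these 4 groups 3, the fit without the libraries numbered 3 called 25, and leaving out 1 library gave between 4 and 11. The time in quizartinib before dexamethasone also differed between these groups.

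Comparisons that share no library could be set side by side. Across 16430 genes, the change with dexamethasone alone and the change it brought to quizartinib at 48 h had Pearson's r = 0.50 and Spearman's rho = 0.36, and genes are not independent replicates. Both comparisons called 353 genes higher and 382 lower, where independent calls would give 50.8 and 50.4, and 14 went opposite ways. Dexamethasone alone and dexamethasone added to quizartinib at 5 days shared 369 higher and 350 lower genes (41.5 and 44 by chance, r = 0.51 and rho = 0.41 across genes). The effects of dexamethasone with quizartinib at 48 h and at 5 days shared 504 higher and 462 lower genes (42.5 and 30.8 by chance, r = 0.65 and rho = 0.52 across genes), and 1 gene went opposite ways.

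In the recovery experiment, comparing survivors of 48 h in 100 nM quizartinib with untreated cells cannot separate survival from drug response. IGF1 was at 284.3 and 151.0 FPKM in the survivors and 5.57 and 0.67 in untreated cells (log2 change of FPKM + 1 5.97 ± 0.96, limma adjusted p = 0.025). PIM1, a STAT5-driven kinase, fell from 65.14 and 56.33 to 10.11 and 6.89 FPKM (-2.72 ± 0.23, adjusted p = 0.0074), and SCD, a fatty acid desaturase, from 95.17 and 143.0 to 10.92 and 11.64 FPKM (-3.26 ± 0.25, adjusted p = 0.0059). BMF rose from 10.94 and 8.72 to 60.05 and 61.70 FPKM (2.52 ± 0.64, adjusted p = 0.049). CD74 rose from 318.2 and 190.7 to 2143 and 840.7 FPKM (2.44 ± 0.46, adjusted p = 0.028). RRM2 fell from 148.8 and 138.6 to 3.07 and 0.65 FPKM (-5.80 ± 1.35, adjusted p = 0.041). FLT3 (0.63 ± 0.34, adjusted p = 0.24), NR3C1 (-0.35 ± 0.18, adjusted p = 0.21), MCL1 (0.46 ± 0.50, adjusted p = 0.54) and BCL2L11 (0.00 ± 0.50, adjusted p = 1) were not called.

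Of 23 cell cycle genes 12 fell (23 adjusted over the list alone, median -3.63, camera adjusted p = 1.19e-11), of 17 MYC targets 10 fell (16 adjusted over the list alone, median -1.51, camera adjusted p = 2.12e-10), NOP16 by 2.49 ± 0.32, and of 18 sterol genes 13 fell (15 adjusted over the list alone, median -1.66, camera adjusted p = 8.17e-11). Each had adjusted p = 0.552 with an estimated correlation. Of 22 FLT3 output genes 8 fell (15 adjusted over the list alone, median -1.21, camera adjusted p = 8.80e-08, and adjusted p = 0.081 with an estimated correlation). Of 16 ATF4 response genes 4 fell (4, and 1 higher, adjusted over the list alone, median -0.52, camera adjusted p = 0.00552), PHGDH by 4.25 ± 0.69, and of 13 mitochondrially encoded genes 4 fell (median -0.77, camera adjusted p = 0.000176), MT-CO2 by 0.99 ± 0.21, each with adjusted p = 0.552 with an estimated correlation. Higher lists were MHC class II (3 of 5, 4 adjusted over the list alone, median 2.44, camera adjusted p = 0.00739), adhesion (5 of 18, 8 adjusted over the list alone, median 0.79, camera adjusted p = 0.00859), lysosome (6 of 18, 8 adjusted over the list alone, median 0.56, camera adjusted p = 0.00424) and FOXO genes (4 of 15, 5 adjusted over the list alone, median 0.88, camera adjusted p = 0.0287), with ITGAM at 2.02 ± 0.22 and CTSB at 2.10 ± 0.25. These also had adjusted p = 0.552 with an estimated correlation. Camera called 13 of 24 lists, none of them with an estimated correlation.

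Limma called 1474 genes higher and 1156 lower in survivors, and the median change over all genes was 0.18. Quantile normalisation moved that median to 0.04 and gave 1142 higher and 1341 lower, and dividing by the sum without mitochondrially encoded genes gave 1112 and 1407. Leaving out 1 library left a group of 1, which cannot tell whether the calls rest on any library (medians 0.16 to 0.20). The highest and lowest entries were short noncoding RNAs, such as MIR6819 (listed at 0 in both untreated libraries, 1159 and 607.5 FPKM in survivors) and SNORD54 (426.7 and 113.7 FPKM in untreated cells, listed at 0 in survivors).

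Survivors after 13 days without drug differed between their replicates. Replicate 1 had MKI67 at 46.67 FPKM and replicate 2 at 0.20 FPKM, against 95.44 and 80.21 in untreated cells and 2.44 and 1.16 in survivors. BMF was at 8.26 and 40.25 FPKM. Mitochondrially encoded genes took 63.18% of the FPKM sum in replicate 1 and 79.22% in replicate 2, against 61.33% to 65.54% in the other groups, and MT-CO1 was listed at 0 in replicate 2 alone. Both replicates shared other changes from untreated cells. C3, the central complement protein (chromosome 19, 6677704 to 6730562), was at 142.5 and 344.8 FPKM against 2.08 and 3.57 (5.89 ± 0.44, limma adjusted p = 0.0089), and DNASE2, a lysosomal DNase, at 22.95 and 43.23 against 0.51 and 0.24 (4.57 ± 0.35, adjusted p = 0.0093). PIM1 (13.20 and 11.02 FPKM, -2.24 ± 0.23, adjusted p = 0.026), SCD (20.89 and 16.64 FPKM, -2.58 ± 0.25, adjusted p = 0.025) and WT1, a transcription factor of leukaemic blasts (1.44 and 0.59 against 12.31 and 13.78 FPKM, -2.83 ± 0.29, adjusted p = 0.026), were lower.

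Limma called 24 genes higher and 45 lower at 13 days against untreated cells. Of 18 sterol genes 2 fell (15 adjusted over the list alone, median -1.04, camera adjusted p = 1.05e-07, and adjusted p = 0.440 with an estimated correlation), and of 22 FLT3 output genes 1 fell (1 adjusted over the list alone, median -0.52, camera adjusted p = 0.0394, and adjusted p = 0.440 with an estimated correlation). For the lists that follow, counts are those adjusted over the list alone. Lower in camera were cell cycle genes (1, median -2.57, adjusted p = 3.46e-07, and adjusted p = 0.481 with an estimated correlation) and MYC targets (10, median -1.04, adjusted p = 3.42e-06, and adjusted p = 0.441 with an estimated correlation). Higher were lysosome genes (7, median 0.64, adjusted p = 3.16e-06, and adjusted p = 0.342 with an estimated correlation), monocyte and macrophage genes (7, and 1 lower, median 1.23, adjusted p = 0.000199, and adjusted p = 0.301 with an estimated correlation) and MHC class II (4, median 2.40, adjusted p = 0.000116) and class I genes (4, median 1.05, adjusted p = 0.00144), the last pair with adjusted p = 0.440 each with an estimated correlation. Camera called 15 of 24 lists, none of them with an estimated correlation. The number of called genes was 2244 without 13 day replicate 1 and 31 without replicate 2, and 30 and 31 without untreated replicates 1 and 2. C3 was not called without untreated replicate 1 and DNASE2 without either untreated library. FLT3 (0.23 ± 0.34, adjusted p = 0.73), NR3C1 (-0.74 ± 0.18, adjusted p = 0.11), BCL2L11 (0.53 ± 0.50, adjusted p = 0.57) and MCL1 (0.76 ± 0.50, adjusted p = 0.41) were not called.

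At 13 days against the survivors, limma called 32 genes higher and 121 lower, with a median change of -0.18 that quantile normalisation moved to 0.02 (64 higher and 98 lower). C3 rose from 18.76 and 20.50 to 142.5 and 344.8 FPKM (3.43 ± 0.44, adjusted p = 0.032), ASS1, which makes argininosuccinate, by 3.34 ± 0.42 and RNASE2, a granule ribonuclease, by 2.23 ± 0.28. PIM3 rose (1.41 ± 0.17), MT-CO2 rose (1.56 ± 0.21) and IFITM1 fell (-1.72 ± 0.25). FLT3 output genes (1 higher of 22, 4 adjusted over the list alone, median 0.55, camera adjusted p = 2.23e-06) had adjusted p = 0.110 with an estimated correlation. Mitochondrially encoded genes (1 of 13, 7 adjusted over the list alone, median 0.85, camera adjusted p = 1.37e-07) and granule genes (1 of 9, 3 adjusted over the list alone, median 0.85, camera adjusted p = 2.97e-05) had adjusted p = 0.592 each with an estimated correlation. Of 19 interferon-stimulated genes 1 was lower (median -0.79, camera adjusted p = 0.0393, and adjusted p = 0.703 with an estimated correlation). Camera called 10 of 24 lists, none of them with an estimated correlation. Without 13 day replicate 2, 2663 genes were called, and 53 without replicate 1, 57 and 51 without survivor replicates 1 and 2.

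**Figure D3:**
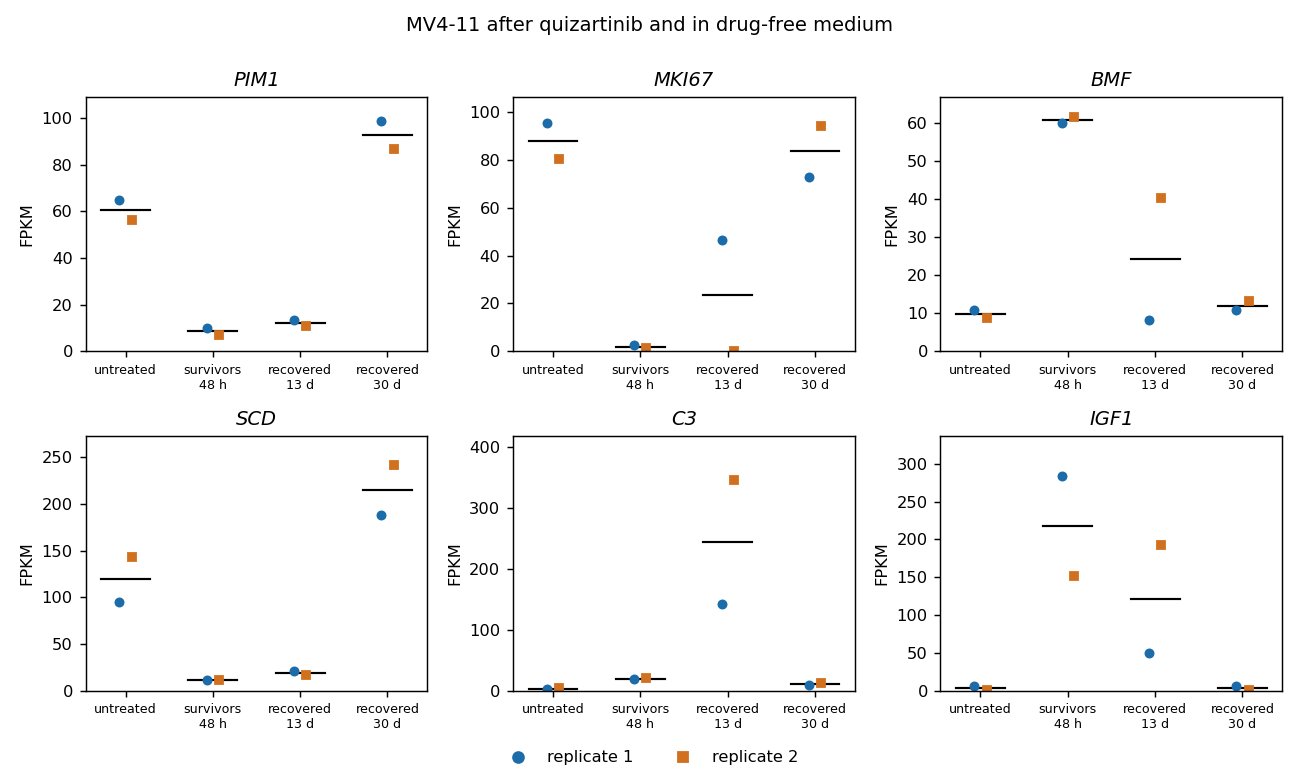
FPKM of genes named in the text in each of the 8 libraries of the recovery experiment, by group. Points are libraries and lines are the mean of 2, and the 13 day libraries lie far apart for MKI67 (46.67 and 0.20 FPKM) and close together for PIM1 (13.20 and 11.02 FPKM).

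Cells 30 days off the drug were set against untreated cells. The labels give no untreated group of 30 days, so culture time may differ. Limma called 14 genes higher and 9 lower. MVD, a mevalonate pathway enzyme, was at 126.9 and 127.9 FPKM against 29.16 and 33.45 (1.99 ± 0.17, adjusted p = 0.015). ALDOC was at 66.05 and 58.27 against 4.83 and 7.56 FPKM (3.16 ± 0.26, adjusted p = 0.014). MIR210HG, a noncoding RNA, was at 41.08 and 44.94 against 0.63 and 0.90 FPKM (4.64 ± 0.45, adjusted p = 0.028). Both were also higher in DMSO replicate 3, without drug. HMGCS1, of the same pathway as MVD, was at 131.6 and 179.2 against 29.16 and 42.89 FPKM without passing (2.09 ± 0.25, adjusted p = 0.091). Of 18 sterol genes 1 rose (16 adjusted over the list alone, median 1.09, camera adjusted p = 3.28e-26, and adjusted p = 0.226 with an estimated correlation). The same list was lower in survivors and at 13 days, so its rise is not a change that persisted. IGF1 was at 6.46 and 1.32 FPKM, PIM1 at 98.73 and 86.72 FPKM and MKI67 at 72.99 and 94.15 FPKM. FLT3 (0.01 ± 0.34), NR3C1 (0.02 ± 0.18), MCL1 (0.10 ± 0.50) and BCL2L11 (-0.44 ± 0.50) were not called (adjusted p = 1 for each).

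Camera called 14 of 24 lists at 30 days, none of them with an estimated correlation, and in the other 13 no gene passed limma over all 18098 genes, of which 611 had an unadjusted p under 0.05. They included inflammatory genes (median 0.77, adjusted p = 9.64e-06) and ATF4 response genes (median 0.43, adjusted p = 1.78e-06), each with adjusted p = 0.383 with an estimated correlation, interferon-stimulated genes (median 0.64, adjusted p = 5.93e-06, and adjusted p = 0.481 with an estimated correlation) and monocyte genes (median 0.34, 1 higher adjusted over the list alone, adjusted p = 0.000388, and adjusted p = 0.226 with an estimated correlation). Only 2 genes were called among protein-coding genes alone and 5 with only these 4 libraries in the fit. The main fit pools the spread of all 8 libraries, the unlike 13 day pair included. Few calls therefore do not show a return to the untreated state. MVD, MIR210HG and ALDOC lost their call with some 1 library left out.

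At 30 days against 13 days, limma called 59 genes higher and 14 lower. SCD went from 20.89 and 16.64 to 188.4 and 241.6 FPKM (3.45 ± 0.25, adjusted p = 0.0061) and HMGCS1 from 12.75 and 14.70 to 131.6 and 179.2 FPKM (3.40 ± 0.25, adjusted p = 0.0062), and both lost their call without 30 day replicate 2. PIM1 (2.84 ± 0.23), WT1 (3.01 ± 0.29) and LSS (3.03 ± 0.25) rose and C3 fell (-4.23 ± 0.44). Of 18 sterol genes 8 rose (18 adjusted over the list alone, median 2.22, camera adjusted p = 1.58e-18) and of 22 FLT3 output genes 1 rose (3 adjusted over the list alone, median 1.00, camera adjusted p = 0.00139), each with adjusted p = 0.299 with an estimated correlation. Adjusted over the list alone, 8 ATF4 response genes were higher (median 1.05, camera adjusted p = 9.61e-05, and adjusted p = 0.512 with an estimated correlation), and 4 MHC class II genes lower (median -2.34, camera adjusted p = 0.00011, and adjusted p = 0.451 with an estimated correlation). Camera alone called the cell cycle genes (median 2.35, adjusted p = 2.03e-06, and adjusted p = 0.629 with an estimated correlation). The mitochondrially encoded genes were called lower (median -0.44, 2 adjusted over the list alone, camera adjusted p = 0.00428, and adjusted p = 0.629 with an estimated correlation), while their mean was 0.08, with MT-CO1 listed at 0 in 13 day replicate 2. Without 13 day replicate 1, 1726 genes were called, 52 without replicate 2 and 35 without either 30 day library.

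The genes that 10 nM quizartinib changed at least 2-fold in the drug experiment were followed in the recovery experiment, which shares no library with it. In survivors the 1524 higher genes had a median log2 change of 1.18, with 95.8% above 0, and the 1666 lower genes -1.28, with 95.5% below 0 (camera p = 6.41e-31 and 1.21e-62, and p = 0.0558 and 0.0614 with an estimated correlation). Across 13550 genes the changes in the drug and the recovery experiment had r = 0.78 and rho = 0.80, with genes not independent replicates, and both called 1047 higher and 990 lower (362 and 353 by chance). The medians against the untreated mean were 0.42 and -0.46 in 13 day replicate 1 and 1.00 and -1.30 in replicate 2. At 30 days against untreated cells they were 0.12 and -0.08 (camera p = 0.00184 and 0.236, and p = 0.512 and 0.864 with an estimated correlation). From 13 to 30 days they moved by -0.57 and 0.85.

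**Figure D4:**
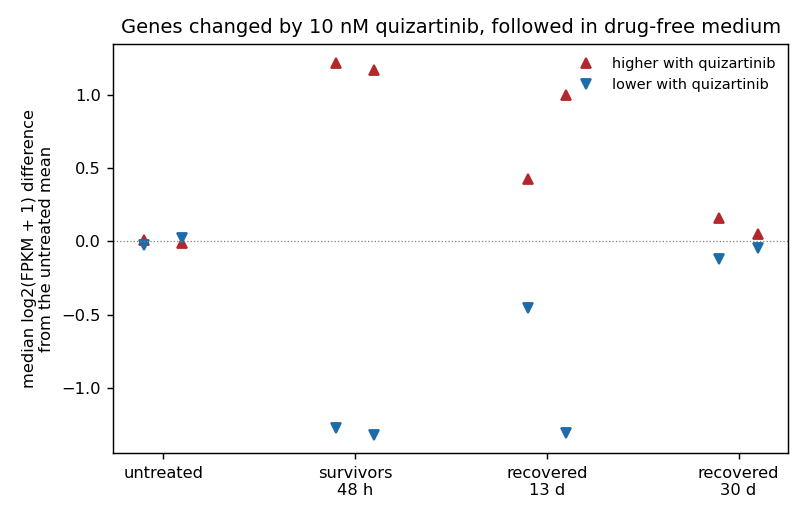
Median log2(FPKM + 1) difference from the untreated mean, in each of the 8 recovery libraries, of genes that quizartinib raised (red, upward triangles) and lowered (blue, downward triangles) in the drug experiment. The values are 1.22 and -1.27 and 1.17 and -1.32 in the survivors, and 0.16 and -0.12 and 0.05 and -0.04 at 30 days.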

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

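All tests of the 3 patterns were chosen after the result was seen, and only the counts of other sample splits were planned before.

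The effect of dexamethasone at 48 h differed with and without quizartinib by a test of the difference itself, which called 367 genes. Among them were E2F8 (3.52), KIF18B (3.38), COL24A1 (3.26), UBE2C (3.08), HJURP (2.72), SRGAP1 (2.69), MKI67 (2.16), CHAC1 (1.855), CDC20 (1.72), RRM2 (1.62) and AURKB (1.61), with positive interactions. Negative ones were HLA-DMB (-5.10), SLC7A11 (-2.91), TLR4 (-2.91), MCEMP1 (-2.31), CX3CR1 (-2.28), SLC44A2 (-1.98), HLA-DRB1 (-1.87), CIITA (-1.50), CD74 (-1.14), CTSG (-1.002), CTSB (-0.83), FKBP5 (-0.66) and ASNS (-0.64). The calls of E2F8, CDC20, CTSG, HLA-DRB1 and MCEMP1 were lost with some 1 library left out. List medians were 0.60 for cell cycle genes, -1.36 for MHC class II, -0.69 for sterol and lipid synthesis, -0.35 for monocyte and macrophage, -0.33 for glycolysis, -0.33 for amino acid and ATF4 response, -0.33 for mitochondrially encoded, -0.29 for FLT3 output, -0.27 for glucocorticoid receptor target, -0.22 for granule and -0.14 for lysosome genes. Of 100 splits of the samples 7, the real one included, called as many genes, and the highest other called 6997. Other splits can bring the quizartinib effect into the contrast, so the share cannot decide about chance.

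The effect of dexamethasone with quizartinib differed between 5 days and 48 h by the same kind of test in 8 genes, among them IQGAP3 (-3.12), CDCA5 (-2.74), MKI67 (-2.11), CENPF (-1.62), TOP2A (-1.52) and CCNB2 (-1.45). List medians were -0.37 for cell cycle genes and 0.57 for MHC class II genes. Of 100 splits 2, the real one included, called as many genes. The other called 2218, which points to a structure of the samples. Other splits mix the dexamethasone effect into the spread within groups, so their low counts do not exclude chance for these 8 genes.

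The 7 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05, and in each 1 split, the real one, called as many genes. Real and highest other counts were 1993 and 760 for dexamethasone against DMSO, 1419 and 1 for the combination against quizartinib at 5 days, and 9764, 10362, 1685, 10313 and 520 against 0 for the others. Of the 10 splits of dexamethasone and DMSO, 4 part all 3 numbered pairs and the highest other of these called 0 genes by edgeR. The 760 genes came from a split with both libraries numbered 3 on one side.

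The libraries numbered 3 of the 48 h groups stood apart in genes such as FOS, EGR1 and DUSP1. A larger share of counts in 7SK and 7SL is argued against, since the median shift of all genes in unscaled counts was at most -0.16 in these libraries. Handling or a library batch shared by them stays open and may be the source. The 100 genes picked in DMSO and dexamethasone had median shifts of 0.98 in quizartinib and 0.88 in the combination at 48 h, higher in 82 and 85 of 100, and 0.16 and 0.19 in the libraries numbered 3 of 5 days. No biological explanation was tested.

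The 13 day replicates differed, with the median of the 23 cell cycle genes at -0.89 and -4.01 against the untreated mean in replicates 1 and 2. A survivors library with a wrong label in place of replicate 2 is argued against by 76 protein-coding genes picked between the replicates numbered 1, where replicate 2 differed from survivors in the same direction with a median of 1.11 (quartiles 0.62 and 1.89, 69 of 76 genes). This rests on the 55 lower genes (median 1.0752, lower quartile 0.66, 54 of 55 genes), while the 21 higher genes alone do not decide (median 1.1981, lower quartile -0.08, 15 of 21 genes). This test was restricted to those genes after a first version over all genes, higher direction, had given a median of 0 (71 of 162 genes), and all genes in the lower direction gave 0.58 (lower quartile 0, 253 of 380 genes). Scaling by the mitochondrial share is argued against by the gap between the medians of quizartinib-higher and quizartinib-lower genes. A wrong factor for a library shifts its genes alike, apart from the added pseudocount, and would leave the gap as in the other replicate, but the gap was 1.42 wider in replicate 2 (2.30 against 0.88, where the largest difference within another group was 0.19). Uneven recovery of the cultures and a sample from outside the study stay open and were not tested.

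Of 23 cell cycle genes 11 were called higher in the combination than with quizartinib at 48 h (median 0.38), and the list was not called with an estimated correlation (adjusted p = 0.155). The libraries numbered 3 are argued against as the cause by the list median of 0.43 without them. TMM holds the median of all genes near 0 (0.0054 here), so that value alone decides nothing about scaling between the libraries. A wrong factor for a library shifts all its genes alike, so the list stood above all genes (0.38 against 0.0054) under any factor. Whether the list rose or most genes fell cannot be told, so scaling stays open. Camera called the list against the other genes at the preset correlation only. Reads of cells without quizartinib mixed into the combination libraries stay open, and the values go both ways. The 11 genes need a median share of 1.9% (quartiles 1.72% and 2.54%). Of 6903 abundant genes 4 lay below the lower quartile in every combination library (PHGDH allows at most 0.501%, CDC45 0.785%, DHCR7 0.817% and MYBL2 1.14%), a test that replaced a first version after its result was seen. In that first version 27 genes of the fixed lists implied a median of -0.559% and 243 other genes 2.27% (quartiles 0.997% and 3.9%).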

How the results depend on the processing

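The tests without the libraries numbered 3, those on protein-coding genes only and those on FPKM divided by the sum without mitochondrially encoded genes were chosen after the result was seen, and the other alternatives were planned. The cause of each change was not tested.

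Without the libraries numbered 3 of the 48 h groups, DDIT4 in quizartinib against DMSO at 48 h was higher (0.55, adjusted p = 0.00369) and KLF2 in quizartinib at 5 days against DMSO was higher (1.95, adjusted p = 1.88e-05), each the reverse of its sign with all libraries. The same fit called 1068 genes for quizartinib at 5 days against 48 h (520 with all libraries), 2758 for the combination against quizartinib at 5 days (1419) and 25 for the difference between the dexamethasone effects (8).

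With only the groups of the contrast in the fit, 579 genes were called for dexamethasone against DMSO (1993), 866 for quizartinib at 5 days against 48 h, 2430 for the combination against quizartinib at 5 days, 189 for the interaction (367) and 3 for the difference between dexamethasone effects. In the recovery experiment this fit called, by limma, 0 genes at 13 days against untreated (69, with 4075 at an unadjusted p under 0.05), 5 at 30 days against untreated (23), 17 at 13 days against survivors (153) and 0 at 30 against 13 days (73, with 3615 at an unadjusted p under 0.05). DESeq2 called 923 genes for quizartinib at 5 days against 48 h, 597 for the interaction and 39 for the difference between dexamethasone effects. With the replicate block these were 885, 572 and 19, and in the recovery experiment 27 at 13 days and 15 at 30 days against untreated and 80 at 13 days against survivors. In paired comparisons the block changed 1 list call, the ribosomal protein genes with quizartinib at 48 h.

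With no filter limma called 727 genes in survivors (2630) and 32 at 13 days against untreated, and a pseudocount of 0.1 gave 14 at 30 days. Among protein-coding genes only, the counts were 370 at 13 days and 2 at 30 days against untreated, 267 at 13 days against survivors and 134 at 30 against 13 days. Of 139 list calls, 7 held with an estimated correlation. With no fold minimum the quizartinib-lower genes were called at 30 days against untreated with the preset correlation (median -0.0715) and not with an estimated one, while in survivors the quizartinib-higher and quizartinib-lower genes were called with an estimated correlation too (limma camera, p = 0.0257 and 0.0313).

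Leaving out 1 library gave 133 to 370 genes for quizartinib at 5 days against 48 h, 818 to 1217 for the combination against quizartinib at 5 days, 218 to 414 for the interaction and 4 to 11 for the difference between dexamethasone effects. In the recovery experiment it gave 39 to 61 in survivors, 30 to 2244 at 13 days and 11 to 30 at 30 days against untreated, 51 to 2663 at 13 days against survivors and 35 to 1726 at 30 against 13 days. A group left with 1 library was assumed to vary like the others. Among named genes of the drug experiment, 3778 results were the same, 49 stronger and 199 weaker with 1 library left out, and in the recovery experiment 846, 52 and 426.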

Other observations

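The genes below were picked here after their values were seen, while the comparisons and the list were planned.

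Single macrophage genes went both ways with dexamethasone, and the fixed monocyte and macrophage list was not called (4 higher and 3 lower of 16, median 0.35, camera adjusted p = 0.107). CD163 (9.00 ± 0.85) and TLR4 (3.17 ± 0.15) rose. LYZ, which encodes lysozyme, went from 685.3 ± 153.4 to 113.5 ± 12.5 CPM with dexamethasone (SD, n = 3 each; log2 fold change -2.59 ± 0.19, edgeR adjusted p = 6.1e-08) and from 791.8 ± 250.4 to 140.7 ± 7.73 CPM when quizartinib was present (-2.49 ± 0.19, adjusted p = 1.2e-07). CSF1R, the macrophage growth factor receptor, rose with quizartinib from 44.79 ± 11.6 to 163 ± 5.88 CPM (1.86 ± 0.20, adjusted p = 3.7e-07) and was at 90.01 ± 6.03 CPM in the combination (-0.86 ± 0.19 against quizartinib, adjusted p = 0.0068). IGF1, raised by quizartinib, fell with dexamethasone alone from 13.8 ± 2.79 to 1.53 ± 0.27 CPM (-3.18 ± 0.17, adjusted p = 1.6e-09) and in the combination to 210 ± 19.6 from 406.8 ± 30.9 CPM (-0.95 ± 0.13, adjusted p = 6.3e-05). KIT, a stem cell receptor kinase, rose with quizartinib from 5.72 ± 1.22 to 34.18 ± 6.95 CPM (2.58 ± 0.29, adjusted p = 6.3e-07) and stood at 35.05 ± 12.8 CPM in the combination (0.04 ± 0.26, adjusted p = 0.96).

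Of the recovery libraries, 13 day replicate 1 listed 21 genes at 0 that had at least 10 FPKM in every other library, and replicate 2 listed 8, against 2 to 7 in the others.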
